A study of Mus musculus with 15 samples.

How the data were processed

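The analysis used 1 deposited table with 168326 transcript lines (88340 with AK, 48232 with Ensembl and 31754 with RefSeq identifiers) and 15 value columns, all matched to samples by name, with 0 unmatched. Values carried a decimal comma and were read as decimal numbers. The unit was not named and was worked out from the values: for 46002 Ensembl transcripts with a known length, 94.1% to 95.0% of low values times transcript length were whole multiples of 1 step per library (tolerance 0.05, where chance gives 10%). The step fits RPKM as deposited by the authors, with 27.01 to 42.6 M reads per library, and 1 read on a 1 kb transcript was 0.023 to 0.037 RPKM. The submitters' notes name CASAVA and bcl2fastq, with no version in the sources used here. The aligner, genome build and annotation of the table are not given in the sources used here.

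A branch for counts was planned in case the table held counts, and its tests, a quasi-likelihood fit and DESeq2, were not run. The table held RPKM, so the planned branch for normalized values was used. Levels were log2(RPKM + 0.5), kept without further scaling, for genes with at least 0.5 RPKM in at least 3 libraries. Transcripts with a symbol made up 145154 lines and 29072 genes, and each gene was represented by its transcript with the highest mean over all libraries. The restriction to lines with a symbol, which left out 23172 lines, was chosen after the table was seen. The fit was limma with empirical Bayes moderation and a mean-variance trend over all 15 libraries and 5 groups (10 residual degrees of freedom, 13869 genes). Adjusted p are from limma with the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The omnibus test was the moderated F-test over control, FGF1, FGF8b and FGF9.

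The same fit was run on made data in which 50 genes were given each known change. Per comparison it recovered 100% of changes of 2 on the log2 scale, 94% to 100% of changes of 1 and 60% to 84% of changes of 0.5 in either direction. Between 5 and 10 unchanged genes were called per comparison, among 172 to 185 calls in all. The made data held far fewer changed genes than most real comparisons, and their noise was drawn independently for each gene. This number of false calls therefore does not carry over to the real comparisons.

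Whole reads were recovered from the steps of the RPKM values for 13854 (99.9%) of the tested genes, within 0.02 read. The inferred transcript length equalled that of the annotation for 90.8% of 3473 Ensembl transcripts compared. These reads gave the read counts, the exact 95% intervals of ratios and the voom alternative. The intervals cover counting error only, and not the spread between samples. Genes with near-identical relatives, such as the Prl2c family, and transcripts that overlap others have uncertain values, because the table does not say how shared reads were assigned or whether the reads marked the strand.

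The replicate numbers in the titles did not pair libraries across groups: 10 of 30 same-number pairs had deviations correlated above 0.1 (range -0.443 to 0.534), and 2 of 15 libraries were closest to their own number in every group. No block was used, and the numbers served as a replicate block in an alternative fit.

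The named genes of a comparison were chosen among those past the threshold with no overlap between the 2 groups of libraries. They also had a mean of at least 1 RPKM in at least 1 of the groups, and predicted gene models were left out. Of these, the 8 with the largest absolute log2 change per direction were named in the main comparisons, and the 5 largest in the others. The largest rises and falls in the text refer to these genes. To these came 8 genes followed throughout (Ucp1, Ppargc1a, Pparg, Fgfr1, Dusp6, Etv4, Ptgs2 and Slc2a1) and up to 4 members per list. Genes of the marker lists and others with few reads in the closing part were picked after the values were seen. Positions are from GENCODE vM21 on GRCm38, an annotation that may differ from that of the table.

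There were 28 gene lists, with 612 members, of which 611 were in the table and 502 were tested. They cover brown thermogenic genes, adipocyte differentiation, preadipocyte and progenitor genes, FGF-ERK feedback, FGF receptors and coreceptors, prostaglandin E2, glycolysis, the mitochondrial respiratory chain, citrate cycle and fatty acid oxidation, cell cycle, extracellular matrix, matrix proteases, contractile genes, chemokines and inflammation, interferon response, ATF4 targets, unfolded protein response, hypoxia, cholesterol synthesis, glucose sensing by MondoA, pentose and hexosamine pathways, and targets of WNT, TGF-beta and BMP. The other 6 hold markers of skeletal muscle, endothelium, macrophages, mural cells, Schwann and neural cells, and bone and cartilage. The list of ATF4 targets also holds Atf4 itself, and the list of glucose sensing by MondoA also holds Mlxip, the gene of MondoA. The lists were written from general knowledge before any comparison was fitted. Members below the level filter were not tested, so counts per list refer to tested members only. Tested were 12 of 22 brown thermogenic, 16 of 28 adipocyte differentiation, 4 of 15 endothelial and 4 of 19 skeletal muscle members. Of the macrophage list and of the bone and cartilage list, 5 of 16 members each were tested. Lists were tested with camera (preset correlation 0.01), which compares a list with all other genes, adjusted over the 28 lists. The alternatives were camera with a correlation estimated per list, and fry. The p of fry tests whether the genes of a list move on balance in 1 direction, its mixed p whether they change in either direction, and neither compares them with other genes.

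Alternatives fixed before the table was seen were trimmed-mean and median-of-ratios scaling, no filter, a replicate block, the 6 libraries of a comparison alone, leaving out each library, a minimum log2 change of 1, summed transcripts and pseudocounts of 0.1 and 1. Alternatives added afterwards were the RefSeq transcript of a gene, lines without a symbol, voom, correction for GC content and leaving out 3 libraries at either end of the axis of GC content, and, for the share of the FGF8b response kept with BAY-876, other pseudocounts and voom. Software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.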

Results

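RNA sequencing measured transcript levels in immortalised brown preadipocytes, the precursor cells of brown fat, made with the SV40 large T antigen from the stromal-vascular fraction of the interscapular brown fat of 129SvEv mice. The 15 libraries formed 5 groups of 3: control cells, and cells treated for 48 h with 5.56 nM FGF1, FGF8b or FGF9, or with FGF8b together with 2 µM BAY-876, an inhibitor of the glucose transporter GLUT1. The FGFs are paracrine fibroblast growth factors, and the series text gives 1 µg/ml heparin, a glycosaminoglycan that helps FGFs bind their receptors, to all of them. The sample labels name heparin for FGF9 alone, and if only these cells had it, FGF9 would differ from FGF1 and FGF8b by heparin too. Between 27.01 and 42.6 M reads stood behind the values of a library: 31.6 to 37.5 M in control, 27.01 to 32.0 M in FGF1, 28.3 to 35.7 M in FGF8b, 37.3 to 41.6 M in FGF9 and 29.6 to 42.6 M in FGF8b plus BAY-876. Levels below are RPKM (reads per kilobase of transcript per M reads), as mean ± SD of 3 libraries per group (n = 3). Changes are log2 fold changes ± SE from limma over 13869 genes, with p-values adjusted by Benjamini-Hochberg. The 0.5 RPKM added before the logarithm shrinks the changes of genes with low levels, so for these a second value from voom on recovered reads, or a ratio of reads with its counting interval, is given. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between samples, which may be technical. The design held no sample with heparin alone or BAY-876 alone, and the labels do not say whether the control cells had heparin or the same 48 h.

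The libraries of a group lay close together, with correlations across genes of 0.9913 to 0.9967 within groups and 0.8786 to 0.9962 between groups. Genes are not independent replicates. The first 3 principal components held 68.3%, 17.2% and 7.1% of the variance, and on the first and second the FGF8b and FGF9 libraries lay together. In limma, 10180 of the 13869 genes differed somewhere among control, FGF1, FGF8b and FGF9. Ucp1, the uncoupling protein of brown fat thermogenesis (chromosome 8, 83290352 to 83298452 in GRCm38), was at 0.0226 ± 0.0232 RPKM in control and 0.0184 ± 0.0161 in FGF1, from 3 and 2 reads over the 3 libraries of each group. It reached 26.7 ± 1.26 in FGF8b and 37.4 ± 2.94 in FGF9, and 0.58 ± 0.192 in FGF8b plus BAY-876. Ppargc1a, the coactivator that drives thermogenic genes, was at 0.318 in control, 0.093 in FGF1, 0.0771 in FGF8b, 0.117 in FGF9 and 1.47 with BAY-876. Fgfr1, the receptor gene with the most transcript among the FGF receptors tested, was at 71, 67.5, 68.2, 71.2 and 94.7 RPKM in the same order.

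**Figure D1:**
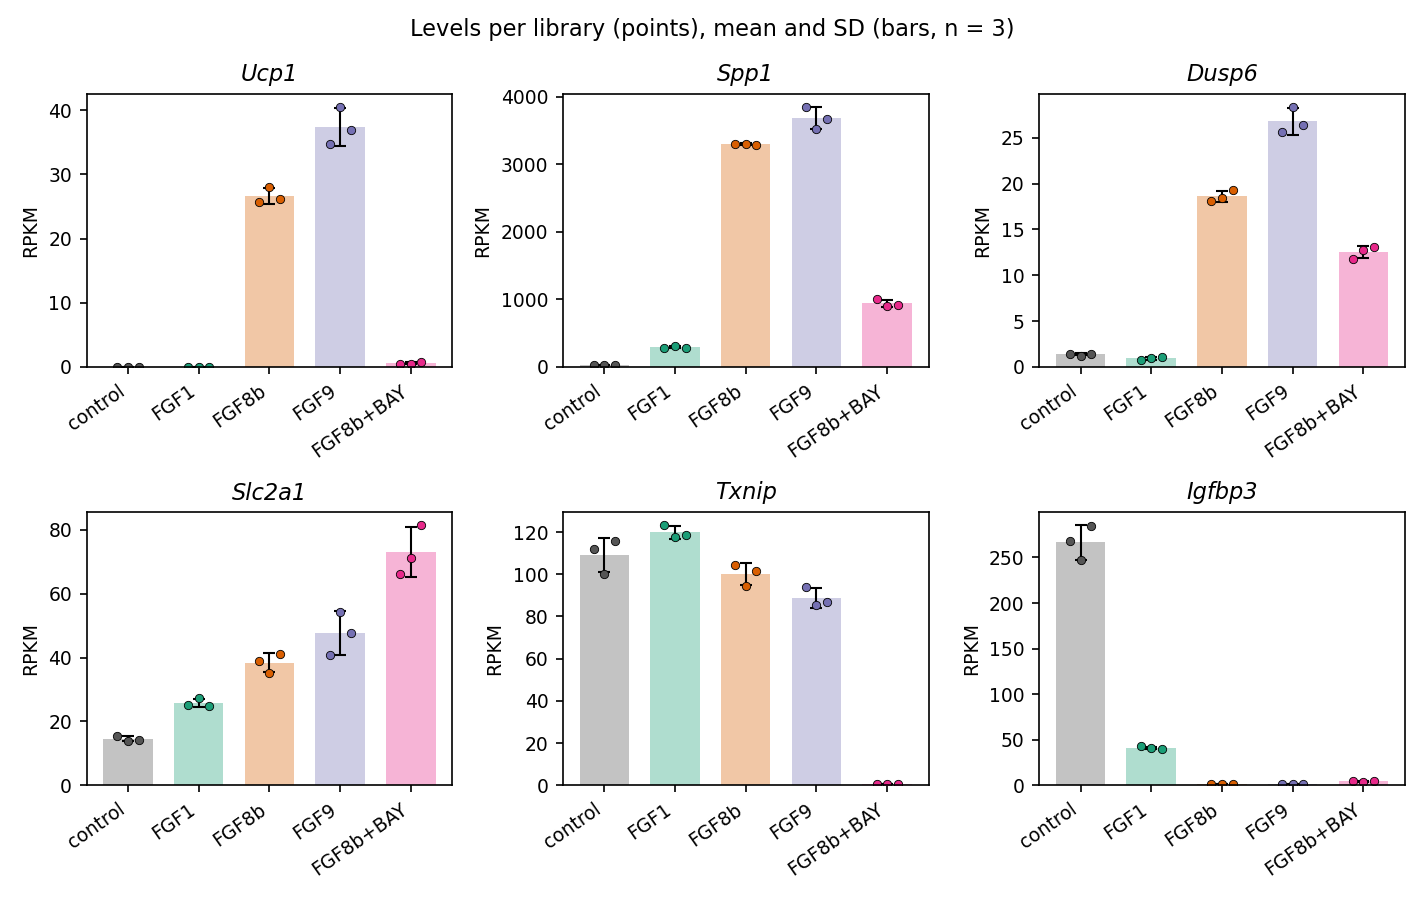
Levels in RPKM (vertical axes, from 0) of 6 genes in the 5 groups, with 1 point per library and bars and error bars for the mean and SD of 3 libraries. Ucp1 stood at 26.7 and 37.4 RPKM in FGF8b and FGF9 and at 0.58 in FGF8b plus BAY-876, and Txnip fell from 100.1 to 0.722 RPKM when BAY-876 was added.

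The comparison of FGF1 with control asked what an FGF that binds every FGF receptor does to these cells. FGF1 raised Spp1, which encodes the secreted phosphoprotein osteopontin, from 31.3 ± 0.687 to 292 ± 15 RPKM, Cilp, a cartilage matrix protein, from 2.86 ± 0.0968 to 53.8 ± 2.3, and Thbs4, the matrix glycoprotein thrombospondin-4, from 5.35 ± 0.328 to 56.1 ± 0.891. The lactate exporter Slc16a3 rose from 3.5 ± 0.692 to 28.6 ± 0.995, and the transcription factor Runx1 from 1.23 ± 0.203 to 9.23 ± 0.367. FGF1 lowered Clec3b (tetranectin) from 36.7 ± 4.97 to 1.41 ± 0.367, the lipid carrier Apod from 277 ± 15.3 to 32.3 ± 4.59 and the lipase Lipg from 17 ± 0.466 to 1.4 ± 0.0643. Ucp1 was not detectable above control at this depth.

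The changes of these genes were 3.20 ± 0.06 for Spp1 (adjusted p = 6.26e-15), 4.01 ± 0.12 for Cilp (adjusted p = 5.01e-12) and 3.27 ± 0.10 for Thbs4 (adjusted p = 5.01e-12). Among the other genes of the 8 largest rises were Ndufa4l2, a hypoxia-induced mitochondrial protein (2.89), S100g, a calcium-binding protein, and Car9, a carbonic anhydrase. S100g had 2 reads in control and 158 in FGF1, a ratio of levels of 92.9 (95% exact interval 25.3 to 774), and Car9 had 5 and 249 reads, a ratio of 58.5 (24.8 to 182). The 8 largest falls held Clec3b (-4.29 ± 0.13, adjusted p = 5.01e-12), Lipg (-3.21), Apod (-3.09), Itih5 (-3.00), the interferon-induced Ifi44l (-2.88), Enpp2, which encodes autotaxin (-2.87), the chemokine Cxcl9 (-2.74) and the neurotrophin receptor Ngfr (-2.71). Of the genes followed in every comparison, Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 1.19 and Slc2a1, which encodes GLUT1, by 0.80. Pparg, the master regulator of fat cell differentiation, changed by -0.81, Ppargc1a by -0.47 (-1.89 with voom), the ERK phosphatase Dusp6 by -0.36 and the ETS factor Etv4 by -0.71 (-1.13 with voom), all lower in FGF1. Fgfr1 differed by -0.07 (adjusted p = 0.522).

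Glycolysis genes rose together under FGF1: 18 of 23 were higher and 1 lower (18 and 2 when adjusted over the list alone), among them Pgk1 (1.64), Pfkl (1.55) and Eno1 (1.51). The camera test gave adjusted p = 1.95e-10, and adjusted p = 0.252 with an estimated correlation. Hypoxia genes were higher for 14 of 20 and lower for 2 (14 and 3 adjusted over the list alone), with Bnip3 at 1.87 and Egln3, an oxygen-sensing hydroxylase, at 1.80 (camera adjusted p = 1.54e-05, adjusted p = 0.351 with an estimated correlation). Cell cycle genes were higher for 27 of 32, and the other 5 did not pass (27 higher adjusted over the list alone). Examples were Aurkb (0.71) and Top2a (0.69), and camera gave adjusted p = 1.61e-12, and adjusted p = 0.0556 with an estimated correlation. Of the unfolded protein response, 16 of 19 genes were higher and 3 did not pass (16 higher adjusted over the list alone), with Pdia6 at 0.83 and Xbp1 at 0.79 (camera adjusted p = 1.95e-10, adjusted p = 0.0556 with an estimated correlation). Cholesterol synthesis genes were higher for 17 of 24 and 7 did not pass (18 higher adjusted over the list alone). Hmgcs1 (0.80), a synthase early in the pathway, was among them (camera adjusted p = 9.04e-06, adjusted p = 0.472 with an estimated correlation). Contractile genes driven by serum response factor were higher for 13 of 19 and lower for 1 (15 and 1 adjusted over the list alone), with Acta2 at 0.97 and Ankrd1 at -0.81 (camera adjusted p = 2.32e-05, adjusted p = 0.312 with an estimated correlation).

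Interferon response genes fell under FGF1: 25 of 26 were lower and 1 higher, also adjusted over the list alone, with a median of -1.13. Rsad2, an antiviral protein, went from 40.5 ± 6.24 to 5.79 ± 1.01 RPKM and Oas1a from 89.6 ± 10.2 to 17.5 ± 0.413 (camera adjusted p = 4.09e-15, adjusted p = 0.295 with an estimated correlation). Of the chemokines and inflammatory genes, 15 of 23 were lower and 3 higher (16 and 3 adjusted over the list alone), with Cxcl10 at -1.75 and Ccl9 at 1.41 (camera adjusted p = 6.35e-05, adjusted p = 0.152 with an estimated correlation). Targets of the amino acid stress factor ATF4 were higher for 11 of 26 and lower for 3 (12 and 5 adjusted over the list alone). Ddit4 (1.47) and Cth (0.80) were among them (camera adjusted p = 0.0233, adjusted p = 0.472 with an estimated correlation). Feedback genes of the FGF-ERK pathway were higher for 4 of 26 and lower for 9 (4 and 10 adjusted over the list alone), with Ccnd1 at -1.43 and Spry1 at -0.65 (camera adjusted p = 0.073). The lists of extracellular matrix (13 higher and 10 lower of 30, 13 and 10 adjusted over the list alone) and matrix proteases (8 and 9 of 22, 8 and 10 adjusted over the list alone) went both ways. The matrix protein Tnc stood at 1.62, elastin (Eln) at -1.50, and the proteases Adamts1 and Mmp3 at -1.31 and -1.18.

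By limma, 4772 genes passed the threshold in FGF1 against control, 2677 higher and 2095 lower. With an absolute log2 change of at least 1, 172 were higher and 360 lower. Among all 13869 tested genes, 6537 had no overlap between the 2 groups of libraries, which chance gives for 10% of genes. Under trimmed-mean scaling the split turned to 2137 higher and 2528 lower. Of 28 fixed lists, 9 passed camera, and none of the 9 kept its call with an estimated correlation, where the smallest adjusted p was 0.0556.

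FGF8b was compared with control to ask what an FGF that prefers the c splice forms of the receptors does. It raised Spp1 to 3301 ± 10.1 RPKM from 31.3 ± 0.687, the retinoic acid-binding protein Crabp1 to 1463 ± 112 from 87 ± 12.3, and the alarmin cytokine Il33 to 85 ± 2.54 from 1.63 ± 0.377. The ligand Areg (amphiregulin) rose to 15.9 ± 0.572 from 0.0853 ± 0.0222 RPKM, and Ucp1 to 26.7 ± 1.26 from 0.0226 ± 0.0232. Igfbp3, a binding protein of insulin-like growth factors, fell from 267 ± 19.1 to 1.32 ± 0.385, the proteoglycan Ogn from 417 ± 43.3 to 4.96 ± 0.428 and Igf1 from 113 ± 9.26 to 2.19 ± 0.763. Every tested target of ATF4 rose, and 25 of 26 interferon response genes fell.

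Ucp1 had 3146 reads in FGF8b and 3 in control, a ratio of levels of 1147 (95% exact interval 392 to 5560), with adjusted p = 1.73e-15. The largest changes upward included Spp1 (6.70 ± 0.06, adjusted p = 9.10e-20), Il33 (5.34 ± 0.12, adjusted p = 7.40e-15), the semaphorin Sema7a (4.92), Crabp1 (4.07), Cth, which makes cysteine (4.03), and the pseudokinase Trib3 (4.03). Areg had 1735 reads against 10, a ratio of 189.7 (103 to 396). The largest changes downward included Igfbp3 (-7.21 ± 0.11, adjusted p = 1.44e-16), Ogn (-6.25), Egfl6 (-5.63), Igf1 (-5.44), the imprinted gene Mest (-5.37) and Apod (-4.98). Clec3b had 3 reads in FGF8b and 3797 in control, which put control higher by a ratio of 1157 (95% exact interval 395 to 5620). Aspn (asporin), with 33 reads against 3696, was higher in control by a ratio of 102 (73 to 149). Dusp6 rose by 3.37, Etv4 by 3.83, Slc2a1 by 1.36 and Ptgs2 by 1.32, while Ppargc1a changed by -0.50 (-1.98 with voom) and Pparg by -0.43. Fgfr1 differed by -0.06 (adjusted p = 0.517) and passed the threshold under trimmed-mean scaling.

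ATF4 targets were higher for 26 of 26, also adjusted over the list alone, with a median of 2.26, among them the glutathione-degrading Chac1 (3.97) and the folate enzyme Mthfd2 (3.42). This list passed camera (adjusted p = 8.30e-17) and kept its call with an estimated correlation (adjusted p = 0.0271). Feedback genes of the FGF-ERK pathway were higher for 16 of 26 and lower for 4, also adjusted over the list alone, with Etv5 at 3.12 and Dusp4 at 3.09 (camera adjusted p = 0.00139, adjusted p = 0.429 with an estimated correlation). Glycolysis genes were higher for 17 of 23 and lower for 2, also adjusted over the list alone, including Hk2 (1.54) and Pgk1 (1.75). Camera gave adjusted p = 2.21e-04, and adjusted p = 0.429 with an estimated correlation. Cell cycle genes were higher for 17 of 32 and lower for 4, also adjusted over the list alone, with Cdt1, which licenses DNA replication, at 0.82 (camera adjusted p = 0.02, adjusted p = 0.429 with an estimated correlation).

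Extracellular matrix genes were lower for 19 of 30 and higher for 8, also adjusted over the list alone, with a median of -1.12. The collagen cross-linking enzyme Lox fell from 754 ± 40.7 to 36.4 ± 6.9 RPKM and periostin (Postn) from 2378 ± 91.8 to 199 ± 7.48 (camera adjusted p = 2.21e-04, adjusted p = 0.429 with an estimated correlation). Matrix proteases were lower for 14 of 22 and higher for 6, with Adamts1 at -3.99 and Adamts5 at -2.84 (camera adjusted p = 0.00204, adjusted p = 0.429 with an estimated correlation). Interferon response genes were lower for 25 of 26, with a median of -2.48, including Ifit3 (-4.04) and Mx1 (-3.90), and higher for 1 (camera adjusted p = 1.74e-13, adjusted p = 0.429 with an estimated correlation). Chemokines and inflammatory genes were lower for 14 of 23 and higher for 6, with Cxcl9 at -4.41 and Cxcl10 at -3.49 (camera adjusted p = 0.00139, adjusted p = 0.429 with an estimated correlation). Cholesterol synthesis genes were lower for 19 of 24 and higher for 1, including Hmgcs1 (-1.11) and Nsdhl (-1.06). Camera gave adjusted p = 3.39e-05, and adjusted p = 0.429 with an estimated correlation. Contractile genes were lower for 11 of 19 and higher for 2, with Tagln at -2.64 and Myl9 at -2.49 (camera adjusted p = 0.00924, adjusted p = 0.429 with an estimated correlation). Preadipocyte and progenitor genes were lower for 13 of 19 and higher for 5, with the progenitor surface markers Ly6a at -4.25 and Pdgfra at -2.79 and with Pi16 at 2.27 (camera adjusted p = 0.00402, adjusted p = 0.429 with an estimated correlation). In each list of this paragraph the counts were the same when adjusted over the list alone.

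Of the list of brown thermogenic genes, 12 of 22 members passed the level filter and were tested. The tested part of the list did not move as a set with FGF8b, with 4 higher, 4 lower and 4 not passing of 12 (the same adjusted over the list alone). Its median was 0.03, its mean 0.31 and its camera direction downward (adjusted p = 0.738), and the median turned to -0.06 under trimmed-mean scaling and to -0.08 after correction for GC content. Prdm16, a determinant of brown fat identity, was at 1.05 (2.12 with voom), the deiodinase Dio2 at -1.16 (-2.17 with voom) and the kinase Pdk4 at -2.27. Adipocyte differentiation genes were lower for 8 of 16 and higher for 3 (8 and 3 adjusted over the list alone), with the lipase Lpl at -2.16 and Dgat2 at 1.30 (camera adjusted p = 0.114). Genes of the prostaglandin E2 list, which also holds genes of other prostaglandins, were higher for 7 and lower for 6 of 14 (7 and 6 adjusted over the list alone). Ptgs1 stood at 1.01 and Ptgfr, the receptor of prostaglandin F, at -1.77. The median of this list was 0.20, its mean -0.02 and its camera direction downward, without passing. Of receptors and coreceptors of FGFs, 10 of 23 were lower and 6 higher (12 and 6 adjusted over the list alone), and Sulf2, which trims the sulfates of heparan sulfate, fell from 34.4 ± 1.96 to 1.05 ± 0.0698 RPKM (camera adjusted p = 0.0869).

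By limma, 8931 genes passed in FGF8b against control, 5238 higher and 3693 lower, and 676 and 1115 with an absolute log2 change of at least 1. Of all 13869 tested genes, 9368 had no overlap between the groups, against 10% by chance. The split was 4137 higher and 4531 lower under trimmed-mean scaling. Of 28 lists, 11 passed camera, and with an estimated correlation that of the ATF4 targets passed.

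FGF9 was compared with control in the same way. Its changes resembled those of FGF8b: Spp1 reached 3686 ± 167 RPKM, Il33 119.5 ± 12.7, Sema7a 74.2 ± 8.9 against 1.16 ± 0.136 in control, and Ucp1 37.4 ± 2.94. Igfbp3 stood at 1.9 ± 0.0476, Ogn at 3.38 ± 0.469 and Igf1 at 2.04 ± 0.174 RPKM, all far below control. Every tested ATF4 target rose and 25 of 26 interferon response genes fell.

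Ucp1 had 5498 reads in FGF9 against 3 in control, a ratio of 1606 (95% exact interval 549 to 7790), with adjusted p = 5.70e-16. Upward, Spp1 changed by 6.86 ± 0.06 (adjusted p = 6.40e-20), Il33 by 5.82, Sema7a by 5.49, Chac1 by 4.13 and Trib3 by 4.11. Areg reached 23.4 ± 2.26 RPKM against 0.0853 ± 0.0222, and the uncharacterised AI593442 had 2701 reads against 15 (ratio 158, 95.5 to 282). Downward, Igfbp3 changed by -6.79 ± 0.11 (adjusted p = 2.02e-16), Ogn by -6.75, Igf1 by -5.49, Mest by -5.44 and Apod by -5.33. Control exceeded FGF9 by a ratio of 176 for Aspn (118 to 275), 867 for Clec3b (370 to 2670) and 291 for Egfl6 (211 to 412). Dusp6 rose by 3.89, Etv4 by 4.04, Ptgs2 by 1.85 and Slc2a1 by 1.66. Ppargc1a changed by -0.41 (-1.49 with voom) and Pparg by -0.57, while Fgfr1 differed by 0.01 (adjusted p = 0.916).

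Under FGF9, 26 of 26 ATF4 targets were higher, also adjusted over the list alone, with a median of 2.40 (camera adjusted p = 2.66e-16, adjusted p = 0.0302 with an estimated correlation). FGF-ERK feedback genes were higher for 19 of 26 and lower for 2, also adjusted over the list alone, with Spry4 at 3.74 (camera adjusted p = 9.75e-05, adjusted p = 0.432 with an estimated correlation). Glycolysis genes were higher for 17 of 23 and lower for 3, also adjusted over the list alone (camera adjusted p = 4.22e-04, adjusted p = 0.487 with an estimated correlation). Extracellular matrix genes were lower for 18 of 30 and higher for 8, also adjusted over the list alone, with Lox at -4.56 and Col6a1 at -2.89 (camera adjusted p = 4.22e-04, adjusted p = 0.432 with an estimated correlation). Interferon response genes had a median of -2.56 (camera adjusted p = 1.73e-13, adjusted p = 0.432 with an estimated correlation). Cholesterol synthesis genes were lower for 19 of 24 and higher for 1, also adjusted over the list alone, with Tm7sf2 at -2.05 (camera adjusted p = 8.31e-06, adjusted p = 0.432 with an estimated correlation). Chemokines (15 lower and 6 higher of 23), matrix proteases (13 and 7 of 22), contractile genes (10 and 4 of 19) and progenitor genes (12 and 6 of 19) also passed camera, in the downward direction. Their camera adjusted p were 0.00163, 0.00642, 0.0266 and 0.00798, and with an estimated correlation 0.432, 0.432, 0.504 and 0.432. Adjusted over the list alone, 15, 14, 11 and 13 genes of these 4 lists were lower and 6, 7, 4 and 6 higher.

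By limma, 9108 genes passed in FGF9 against control, 5369 higher and 3739 lower, and 778 and 1164 with an absolute log2 change of at least 1. No overlap between the groups was seen for 9121 of the 13869 tested genes, against 10% by chance. Trimmed-mean scaling shifted the median of all genes by -0.101 and gave 4268 higher and 4610 lower. Of 28 lists, 10 passed camera, and with an estimated correlation that of the ATF4 targets passed.

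**Figure D2:**
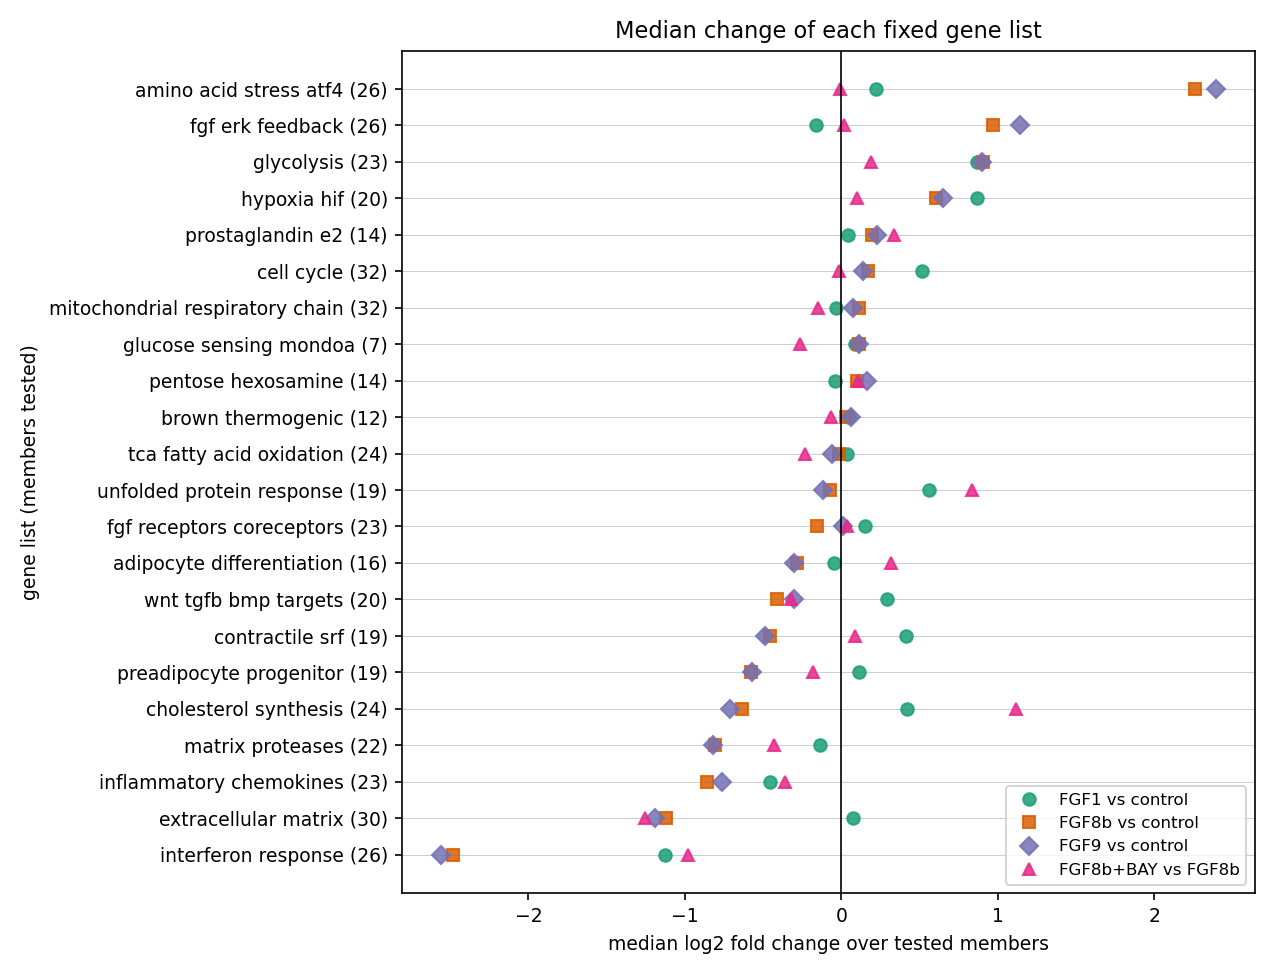
Median log2 fold change over the tested members (horizontal axis) of 22 fixed gene lists (vertical axis, number of members in brackets) in 4 comparisons, 1 symbol each. The ATF4 targets stood at 2.26 and 2.40 with FGF8b and FGF9 against 0.22 with FGF1, and the interferon response list was lowest in the 3 comparisons with control.

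The direct comparisons of ligands asked how the FGFs differ from one another. Against FGF1, FGF8b gave higher Ucp1, Etv4, Il33, Areg and Car6, a secreted carbonic anhydrase, and lower Aspn, Mfap4, Lox, Itga11 and Mest. Etv4 stood at 23.5 ± 1.33 against 0.536 ± 0.073 RPKM (4.54 ± 0.13, adjusted p = 1.44e-13), Il33 at 85 ± 2.54 against 3.46 ± 0.324 (4.43) and Lox at 36.4 ± 6.9 against 1010 ± 10.49 (-4.79 ± 0.10, adjusted p = 6.60e-15). Itga11, a collagen-binding integrin, differed by -4.68 (-7.63 with voom), the microfibril protein Mfap4 by -4.87 and Mest by -4.66. Ucp1 had 3146 reads against 2, a ratio of 1463 (95% exact interval 405 to 12100). Areg had a ratio of 57.6 (39.7 to 87), Car6 of 34.7 (23.7 to 52.9), and Aspn was higher in FGF1 by 59.8 (42.4 to 87). Dusp6 (3.73), Slc2a1 (0.56) and Pparg (0.38) were higher in FGF8b. Ptgs2 (0.13, adjusted p = 0.238), Ppargc1a (-0.04, adjusted p = 0.789) and Fgfr1 (0.01, adjusted p = 0.899) did not pass.

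ATF4 targets were higher in FGF8b than in FGF1 for 24 of 26, also adjusted over the list alone (median 2.20, camera adjusted p = 8.28e-17, adjusted p = 0.0271 with an estimated correlation). FGF-ERK feedback genes were higher for 19 of 26 and lower for 2 (19 and 3 adjusted over the list alone), with Etv5 at 3.66 and Ccnd1 (cyclin D1) at 3.62 (camera adjusted p = 3.97e-06, adjusted p = 0.232 with an estimated correlation). Cholesterol synthesis genes were lower for 24 of 24, with Hmgcs1 at -1.91 (camera adjusted p = 1.08e-10, adjusted p = 0.232 with an estimated correlation). Extracellular matrix genes were lower for 23 of 30 and higher for 5 (camera adjusted p = 1.53e-07, adjusted p = 0.232 with an estimated correlation). Contractile genes were lower for 15 of 19 and higher for 2, with Tagln at -3.20 and Acta2 at -2.80 (camera adjusted p = 3.59e-06, adjusted p = 0.232 with an estimated correlation). The unfolded protein response was lower for 14 of 19 and higher for 1, with Calr at -1.48 (camera adjusted p = 1.19e-05, adjusted p = 0.232 with an estimated correlation). Interferon response genes were lower for 23 of 26 (median -1.11, camera adjusted p = 3.60e-08, adjusted p = 0.39 with an estimated correlation). The counts of the last 5 lists were the same adjusted over the list alone. By limma, 8312 genes passed, 4618 higher and 3694 lower, and 526 and 860 with an absolute log2 change of at least 1. Under trimmed-mean scaling the split turned to 4047 higher and 4217 lower. No overlap was seen for 9551 of the 13869 tested genes, against 10% by chance, and 13 lists passed camera, of which that of the ATF4 targets passed with an estimated correlation.

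Against FGF1, FGF9 gave the same kind of difference, with Etv4 at 4.75, Dusp6 at 4.25, Il33 at 4.92, Lox at -4.98, Ogn at -5.09, Mfap4 at -5.17 and Mest at -4.74. Ucp1 had 5498 reads against 2, a ratio of 2049 (95% exact interval 567 to 16900), Areg a ratio of 84.5 (58.4 to 127), and Aspn was higher in FGF1 by 103 (69 to 161). Slc2a1 (0.86) and Ptgs2 (0.66) were higher in FGF9. Pparg (0.24, adjusted p = 0.0673), Ppargc1a (0.06, adjusted p = 0.654) and Fgfr1 (0.08, adjusted p = 0.375) did not pass, and Pparg passed with the replicate number as a block (adjusted p = 0.043), with the RefSeq row of the gene (0.0474) and without FGF9 replicate 2 (0.0411). ATF4 targets were higher for 24 of 26, also adjusted over the list alone (camera adjusted p = 3.21e-16, adjusted p = 0.0307 with an estimated correlation). By limma, 8586 genes passed, 4817 higher and 3769 lower, and 630 and 898 with an absolute log2 change of at least 1. The split turned to 4115 higher and 4355 lower under trimmed-mean scaling and to 4234 and 4251 under median-of-ratios scaling. Of the tested genes, 9199 of 13869 had no overlap, against 10% by chance, and 12 lists passed camera, of which that of the ATF4 targets passed with an estimated correlation.

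FGF9 and FGF8b differed little from each other. Spry4, a feedback inhibitor of receptor tyrosine kinases, stood at 10.8 ± 0.1001 in FGF9 against 6.13 ± 0.348 RPKM in FGF8b (0.77 ± 0.08, adjusted p = 5.00e-04), the urokinase Plau at 33.4 ± 1.76 against 20.7 ± 2.39 (adjusted p = 0.0011) and the early response factor Egr1 at 16.4 ± 0.426 against 10.3 ± 0.866 (adjusted p = 0.00116). Aff2 (0.72, 1.09 with voom, adjusted p = 0.0495) and Adcy8 (0.67, 1.07 with voom, adjusted p = 0.0227) were the other genes of the 5 largest rises. The prostaglandin receptor Ptgfr, at 1.94 ± 0.215 against 3.59 ± 0.0414 (adjusted p = 0.00101), the imprinted RNA H19, at 54.8 ± 4.76 against 95.8 ± 16.9 (adjusted p = 0.0138), Il15 (-0.61), Mme (-0.54) and Lrrc17 (-0.53) were lower in FGF9. Dusp6 (0.52, adjusted p = 0.0227) and Ptgs2 (0.53, adjusted p = 0.0227) were also higher in FGF9. Of the fixed lists, members past the threshold were also Adamts5 (-0.44), Cxcl12 (-0.34), Grem1 (0.44) and Pdgfra (-0.38). Ucp1 was at 37.4 ± 2.94 against 26.7 ± 1.26 RPKM (0.48, adjusted p = 0.108) and passed with a pseudocount of 1 and with voom. Slc2a1 (0.30, adjusted p = 0.453), Etv4 (0.22, adjusted p = 0.814), Pparg (-0.14, adjusted p = 0.9), Ppargc1a (0.09, adjusted p = 0.955) and Fgfr1 (0.07, adjusted p = 0.954) did not pass.

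FGF-ERK feedback genes were higher in FGF9 than in FGF8b for 3 of 26, and for 7 adjusted over the list alone (median 0.19, camera adjusted p = 4.83e-13, adjusted p = 0.101 with an estimated correlation). By limma, 41 genes passed, 28 higher and 13 lower, and 977 had an unadjusted p under the same threshold. The groups did not overlap for 1504 of the 13869 tested genes, near the 10% that chance gives. None had an absolute log2 change of at least 1. The count moved with the processing: 64 genes passed with voom, and 0 in limma on the 6 libraries of these groups alone, where 804 passed unadjusted and where each of the genes named as past the threshold lost its call. Without FGF9 replicate 3, Dusp6 (adjusted p = 0.11), Ptgs2 (0.109) and H19 (0.0765) lost their calls, and of the genes named here as past the threshold Spry4, Plau, Egr1 and Ptgfr passed whichever library was left out. Leaving out a library gave 6 genes without FGF9 replicate 3, 7 without FGF8b replicate 2, 10 without FGF8b replicate 1 or FGF9 replicate 2, and 17 without FGF8b replicate 3. Of 28 lists, 6 passed camera: besides FGF-ERK feedback these were the respiratory chain, the citrate cycle, interferon response and cholesterol synthesis, downward, and the ATF4 targets, upward. None of the 6 kept its call with an estimated correlation.

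Between the ligands, FGF8b and FGF9 shared 4852 genes higher and 3419 lower than control, where independent calls would share 2028 and 996. Their log2 changes correlated across genes at 0.989, and the covariance was 0.654, against 0.0073 in simulated unchanged groups set against the same control libraries. FGF1 and FGF8b shared 1555 genes higher and 1372 lower (1011 and 558 if independent), with a correlation of 0.52 and a covariance of 0.172, and 500 genes were higher with FGF1 and lower with FGF8b and 318 the reverse, fewer than the 713 and 791 if independent. FGF1 and FGF9 shared 1557 higher and 1380 lower (1036 and 565 if independent), with a correlation of 0.506 and a covariance of 0.175. Simulated unchanged groups against the same controls gave a correlation of 0.502 for the first of these pairs and 0.501 for the second. A correlation near 0.5 therefore does not by itself tell shared changes from shared controls, while both covariances lay far above the simulated 0.0073, and part of the excess of shared genes may come from the control libraries, which enter every comparison. With an absolute log2 change of at least 1, FGF1 and FGF8b shared 67 genes higher and 326 lower, FGF1 and FGF9 67 and 320, and FGF8b and FGF9 633 and 1068.

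**Figure D3:**
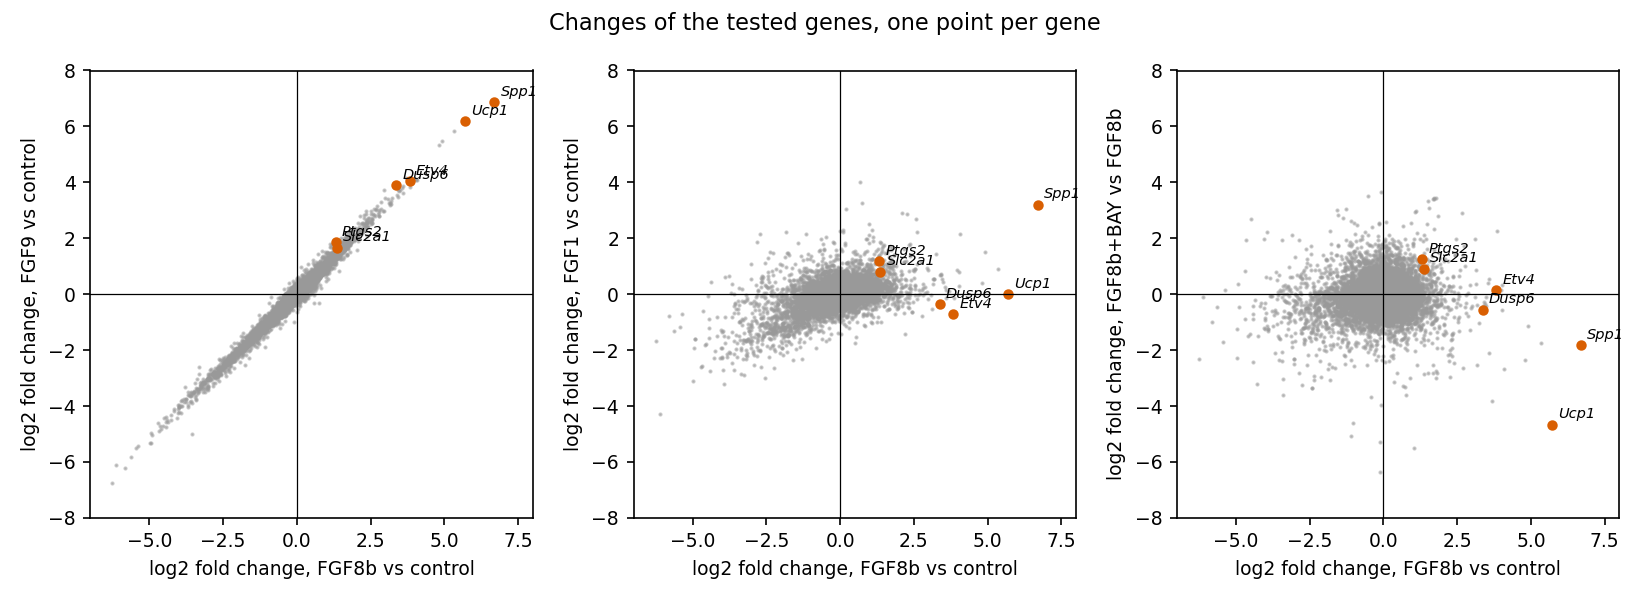
Log2 fold changes of the 13869 tested genes, 1 point per gene, with the change from control to FGF8b on the horizontal axes and on the vertical axes that from control to FGF9 (left), from control to FGF1 (middle) and from FGF8b to FGF8b plus BAY-876 (right). Ucp1, Spp1, Dusp6, Etv4, Ptgs2 and Slc2a1 are marked, and the correlation across genes in the left panel is 0.989. Igfbp3, at -7.21 with FGF8b, lies beyond the left end of the horizontal axes and is not shown.

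BAY-876 was added to FGF8b to ask which parts of the FGF8b response need glucose uptake through GLUT1. Txnip, a glucose-responsive inhibitor of glucose uptake, fell from 100.1 ± 5.19 to 0.722 ± 0.0986 RPKM, and its relative Arrdc4 from 9.58 ± 1.28 to 0.995 ± 0.526. Ucp1 fell from 26.7 ± 1.26 to 0.58 ± 0.192, lumican (Lum) from 24.9 ± 1.98 to 0.0563 ± 0.02999 and the collagen Col3a1 from 579 ± 58.6 to 23.4 ± 2.26. In control, Txnip stood at 109 ± 8.02, Lum at 11.8 ± 0.955 and Col3a1 at 1191 ± 140 RPKM. FGF8b had therefore not raised Txnip or Col3a1, and with BAY-876 each of these genes lay far below control. Without a group of BAY-876 alone, its own effect cannot be told from a loss of the FGF8b response. Of the chaperones of the endoplasmic reticulum, Sdf2l1 rose from 2.95 ± 0.43 to 27.9 ± 2.24, Hyou1 from 23.1 ± 0.391 to 77.3 ± 2.56 and Calr from 275 ± 8.37 to 791 ± 25.7. Slc2a1, the gene of the inhibited transporter, rose from 38.4 ± 3.03 to 73 ± 7.83 RPKM.

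Txnip changed by -6.37 ± 0.07 (adjusted p = 4.70e-18), Ucp1 by -4.67 ± 0.11 (adjusted p = 4.78e-14), from 3146 to 81 reads, H19 by -5.09, Col3a1 by -4.60 ± 0.10 (adjusted p = 1.40e-14) and Col15a1 by -3.67. FGF8b alone exceeded the group with BAY-876 by a ratio of 424 for Lum (95% exact interval 230 to 885), 174 for the chemokine Ccl11 (74.1 to 538) and 582 for AI593442 (199 to 2820). Upward, the phosphatase Ppef1 changed by 3.66 ± 0.20 (adjusted p = 4.58e-10), the surface protein Cd24a by 3.51, the pentraxin Nptx1 by 3.34 and Sdf2l1 by 3.05. Prl2c3 (3.44), Prl2c2 (3.43), Prl2c5 (3.40) and Prl2c1 (3.07) are near-identical paralogs of the proliferin family, so the share of each in the reads is uncertain. Ppargc1a rose by 1.77 (4.18 with voom), Ptgs2 by 1.24, Slc2a1 by 0.92, Pparg by 0.59 and Fgfr1 by 0.47. Dusp6 changed by -0.55, and Etv4, at 0.15 (adjusted p = 0.343), did not pass.

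Unfolded protein response genes were higher for 18 of 19 and 1 did not pass (18 higher adjusted over the list alone), with a median of 0.83 and Manf at 1.64. This list passed camera (adjusted p = 5.70e-14) and kept its call with an estimated correlation (adjusted p = 0.0244). Cholesterol synthesis genes were higher for 23 of 24 and 1 did not pass (23 higher adjusted over the list alone), with Mvd at 1.91 and Lss at 1.79 (camera adjusted p = 4.88e-14, adjusted p = 0.262 with an estimated correlation). Extracellular matrix genes were lower for 25 of 30 and higher for 1, also adjusted over the list alone, with Dcn (decorin) falling from 806 ± 16.6 to 65.2 ± 7.9 RPKM (camera adjusted p = 4.89e-12, adjusted p = 0.175 with an estimated correlation). Interferon response genes were lower for 20 of 26 and higher for 1, also adjusted over the list alone, with Ifit1 at -1.71 (camera adjusted p = 7.45e-04, adjusted p = 0.702 with an estimated correlation). Chemokines were lower for 13 of 23 and higher for 1, also adjusted over the list alone, with Cx3cl1 at -1.76 and Il33 at -1.75 (camera adjusted p = 0.0129, adjusted p = 0.315 with an estimated correlation). Genes of the citrate cycle and fatty acid oxidation were lower for 14 of 24 and higher for 3, also adjusted over the list alone, with Acadvl at -1.64 (camera adjusted p = 0.0327, adjusted p = 0.175 with an estimated correlation). Contractile genes were higher for 9 of 19 and lower for 3, also adjusted over the list alone, with Tagln at 0.96 (camera adjusted p = 0.0416, adjusted p = 0.684 with an estimated correlation).

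ATF4 targets went both ways with BAY-876, 8 higher and 12 lower of 26, also adjusted over the list alone, with Atf3 at 1.01 and Nupr1 at -0.86 (camera adjusted p = 0.706), and a median of -0.01 that turned to 0.07 under trimmed-mean scaling. FGF-ERK feedback genes were higher for 10 and lower for 12 of 26 (11 and 12 adjusted over the list alone), with Fosl1 at 2.34, Dusp4 at 1.99 and Etv1 at -1.61 (camera adjusted p = 0.755). Glycolysis genes were higher for 11 and lower for 4 of 23 (11 and 5 adjusted over the list alone), with Hk2 at 1.20 (camera adjusted p = 0.0696). Genes of the list of the glucose sensor MondoA were lower for 4 of 7 and 3 did not pass (4 lower adjusted over the list alone), with Klf10 at -0.36 beside Txnip and Arrdc4 (camera adjusted p = 0.0696). Mitochondrial respiratory chain genes were lower for 14 of 32 and higher for 3, also adjusted over the list alone, with Ndufv2 at -0.67 (camera adjusted p = 0.0696). Adipocyte differentiation genes were higher for 9 and lower for 5 of 16, also adjusted over the list alone, with the lipid synthesis enzyme Fasn at 1.84 and Plin4 at 1.77 (camera adjusted p = 0.0696). Genes of the prostaglandin E2 list were higher for 8 and lower for 5 of 14 (8 and 6 adjusted over the list alone), with the prostacyclin synthase Ptgis at -2.17 and the exporter Abcc4 at 1.70 (camera adjusted p = 0.565). Brown thermogenic genes were higher for 3 and lower for 5 of 12, also adjusted over the list alone, with Ebf2 at -0.87 (camera adjusted p = 0.862), and a median of -0.06 that turned to 0.04 after correction for GC content.

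By limma, 7941 genes passed when BAY-876 was added, 3117 higher and 4824 lower, and 421 and 533 with an absolute log2 change of at least 1. No overlap was seen for 8691 of the 13869 tested genes, against 10% by chance. The split was 3928 higher and 3998 lower under median-of-ratios scaling. Of 28 lists, 7 passed camera, and with an estimated correlation that of the unfolded protein response passed.

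Of the 676 genes that FGF8b raised by at least 1 on the log2 scale, BAY-876 lowered 81 (12%) and raised 60 (8.9%) by at least 1. Of the 1115 that FGF8b lowered, BAY-876 raised 67 (6%) and lowered 179 (16.1%) further. Independent calls would give 26, 21, 34 and 43 genes. Without the minimum change, 1934 genes were higher with FGF8b and then lower with BAY-876 (1822 if independent), 1230 higher and then higher (1177), 841 lower and then higher (830) and 1449 lower and then lower (1285). The log2 changes of both steps correlated across genes at 0.073. Because the FGF8b libraries enter both steps with opposite signs, simulated unchanged groups gave -0.502, and these counts describe the overlap without testing it.

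The combined treatment was also compared with control. Car6 reached 69 ± 2.97 RPKM against 0.523 ± 0.168 and Avil (advillin), an actin-binding protein, 28.4 ± 1.49 against 0.111 ± 0.0351. Ogn fell from 417 ± 43.3 to 0.603 ± 0.0219 RPKM (-8.56 ± 0.09, adjusted p = 1.45e-18), Ifi27l2a from 596 ± 71.2 to 2.86 ± 0.861 (-7.50), Apod to 1.36 ± 0.44 (-7.25), Igf1 to 0.308 ± 0.144 (-7.15) and the complement protease C1s from 340 ± 29.6 to 2.17 ± 0.471. Prl2c3 (5.22), Prl2c2 (5.13) and Prl2c5 (5.11) rose, with the same limit on paralogs. Ucp1 had 81 reads against 3, a ratio of 25.7 (95% exact interval 8.5 to 127), and Ppargc1a was higher by 1.27 (2.20 with voom). Ptgs2 (2.56), Slc2a1 (2.28), Dusp6 (2.82), Etv4 (3.98) and Fgfr1 (0.42) were higher than in control, and Pparg (0.17, adjusted p = 0.186) did not pass.

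Of the lists, 26 of 26 ATF4 targets were higher than in control, also adjusted over the list alone (median 2.30, camera adjusted p = 3.34e-14, adjusted p = 0.0486 with an estimated correlation). Extracellular matrix genes were lower for 25 of 30, also adjusted over the list alone, with a median of -2.73 (camera adjusted p = 2.99e-11, adjusted p = 0.207 with an estimated correlation). Col1a1 fell from 433 ± 79.5 to 9.66 ± 1.86 RPKM and Col6a2 from 188 ± 19.1 to 2.42 ± 0.237. Interferon response genes were lower for 25 of 26, also adjusted over the list alone, with a median of -3.47 (camera adjusted p = 2.99e-11, adjusted p = 0.425 with an estimated correlation). By limma, 10083 genes passed, 5106 higher and 4977 lower, and 1091 and 1578 with an absolute log2 change of at least 1. The split turned to 4860 higher and 5205 lower under trimmed-mean scaling and to 5034 and 5045 under median-of-ratios scaling. No overlap was seen for 10170 of the 13869 tested genes, against 10% by chance, and 10 lists passed camera, of which that of the ATF4 targets passed with an estimated correlation.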

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

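The tests in this part were all chosen only after the results they concern had been seen. Table lines without a gene symbol, which are not used in the comparisons, also held changes. Of 3560 such lines that passed the same filter, 37 were at least 1 log2 unit higher in FGF1 than in control, 113 in FGF8b and 125 in FGF9. Past the threshold of limma were 446 higher and 364 lower for FGF1, 1268 and 549 for FGF8b, and 1187 and 588 for FGF9. What these transcripts encode was not tested.

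The same 6 libraries of a comparison can be divided into 2 groups of 3 in 10 ways. The real division gave 4772 genes in limma for FGF1 against control, 8931 for FGF8b, 9108 for FGF9 and 10083 for FGF8b plus BAY-876, 7941 for BAY-876 added to FGF8b, 8312 for FGF8b against FGF1, 8586 for FGF9 against FGF1 and 41 for FGF9 against FGF8b. In each comparison 1 of 10 splits, the real one, reached its own count, and the highest other count was 0. 10 splits are too few for a share under 0.05. For the 4 groups of control and ligands, the real grouping gave 10180 genes, 1 of 100 splits reached that number, and the highest other split gave 2667.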

How the results depend on the processing

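The alternatives with the RefSeq transcript, voom, GC correction and libraries at the GC ends were chosen only after results had been seen. The planned count branch with DESeq2 was not run, because the table held RPKM. Requiring an absolute log2 change of at least 1 left 532 genes for FGF1 against control (172 higher, 360 lower), 1791 for FGF8b (676, 1115), 1942 for FGF9 (778, 1164) and 2669 for FGF8b plus BAY-876 (1091, 1578). It left 954 for BAY-876 added to FGF8b (421, 533), 1386 for FGF8b against FGF1 (526, 860), 1528 for FGF9 against FGF1 (630, 898) and 0 for FGF9 against FGF8b (0 higher, 0 lower in limma, unadjusted 977 without the minimum). With that minimum, FGF1 and FGF8b shared 67 genes higher and 326 lower, FGF1 and FGF9 67 and 320, and FGF8b and FGF9 633 and 1068. Of the genes moved by FGF8b, 60 went higher and then higher with BAY-876, 179 lower and lower, 81 higher and then lower and 67 lower and then higher.

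FGF9 against FGF8b, at 41 genes (28 higher, 13 lower), moved most. No filter gave 8 lower, a pseudocount of 0.1 gave 27 (17 higher), the RefSeq transcript 69 (52 higher), voom 64 (51 higher) and GC correction 62 (23 lower). Without the 3 libraries at the high-GC end 15 passed (10 higher, 5 lower), and with only the 6 libraries 0 (0 higher, 0 lower in limma, 804 unadjusted). The cause was not tested. A fit on 6 libraries has fewer degrees of freedom. The same cut gave fewer genes for FGF1 against control (4727 against 4772), FGF8b (8675 against 8931) and FGF9 (8398 against 9108). It also gave fewer for FGF8b plus BAY-876 against control (9745 against 10083) and for BAY-876 added to FGF8b (7826 against 7941). For FGF8b against FGF1 it gave more, 8886 against 8312. With the replicate block 30 genes passed for FGF9 against FGF8b. Leaving out 1 library gave 6 to 35 (4 to 24 higher, 2 to 11 lower). In the other comparisons it gave 3911 to 4373 for FGF1, 8126 to 8478 for FGF8b, 8429 to 8811 for FGF9, 9552 to 9732 for FGF8b plus BAY-876, 7217 to 7612 for BAY-876 added to FGF8b, 7539 to 7944 for FGF8b against FGF1 and 7858 to 8260 for FGF9 against FGF1.

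Gene lists past the threshold went from 9 with camera to 0 with an estimated correlation (smallest adjusted p = 0.0556) and 23 with fry for FGF1 against control, from 11 to 1 and 24 for FGF8b, from 10 to 1 and 25 for FGF9, and from 7 to 1 and 20 for BAY-876 added to FGF8b. For FGF8b plus BAY-876 against control they went from 10 to 1 and 27, for FGF8b against FGF1 from 13 to 1 and 26, for FGF9 against FGF1 from 12 to 1 and 25, and for FGF9 against FGF8b from 6 to 0 (smallest adjusted p = 0.101) and 2. fry asks a different question, so its counts do not compare with those of camera. The replicate block changed no call of a list.

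Of 893 results for named genes, 833 passed and 49 of these lost the call in some setting. In 4 the direction reversed. Phex in FGF8b vs control went from 0.24 to -0.53 with its transcripts summed and -0.22 with the RefSeq transcript, and Phex in FGF9 vs control from 0.32 to -0.46 and -0.17. Csf1r in FGF8b+BAY vs FGF8b went from 0.28 to -0.033 with the RefSeq transcript, and Csf1r in FGF8b+BAY vs control from 0.36 to -1.15 summed and -0.53 with the RefSeq transcript. Other transcripts of a gene enter there, so its direction depends on the transcript.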

Other observations

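The tests of explanations in this part were all chosen only after the results they concern had been seen. Apart from Egfl7 and Spp1, the tested markers of other cell types named here stood below 10 RPKM in all 5 groups. The endothelial receptor Kdr stood at 6.18 ± 0.726 RPKM in control, 0.709 ± 0.078 in FGF1, 0.0284 ± 0.0145 in FGF8b and 0.048 ± 0.0182 in FGF9. With BAY-876 added to FGF8b, Kdr stood at 0.421 ± 0.0394 RPKM, with 120 reads against 7 in FGF8b alone. The endothelial marker Vwf had 220 reads against 2 there, while Egfl7 went the other way (-1.64). Of the endothelial list, 2 of 4 genes were lower with FGF1 and 2 with FGF8b, where 1 (Egfl7, 0.80) was higher (camera adjusted p = 0.0556 and 0.204). Ngfr, a marker of Schwann cells, fell from 6.99 ± 0.602 RPKM to 0.641 ± 0.0623, 0.124 ± 0.0554 and 0.105 ± 0.0232 with FGF1, FGF8b and FGF9, and 4 of 7 genes of its list were lower and 1 higher with FGF8b (camera adjusted p = 0.178). Of the macrophage list, 2 of 5 genes were lower and 1 higher with FGF8b (camera adjusted p = 0.35), with Cd14 at -0.62. Of mural markers, 4 of 6 were higher and 2 lower (camera adjusted p = 0.728), with Cspg4 at 0.93. The muscle list had 4 tested genes, with 1 higher (camera adjusted p = 0.728): Chrna1, with 120 reads in FGF8b and 1 in control, a ratio of 131 (95% exact interval 23.1 to 5230). Of the bone and cartilage list, 3 of 5 genes were higher and 1 lower (camera adjusted p = 0.333), Spp1 most. The rises of Phex (0.24, limma adjusted p = 0.0388) and Runx2 (0.23, limma adjusted p = 0.0455) were small, and that of Phex reversed with other transcripts of the gene. The counts of these lists were the same when adjusted over the list alone.

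Among the lists not yet described, targets of WNT, TGF-beta and BMP were higher for 6 and lower for 10 of 20 with FGF8b (camera adjusted p = 0.0869). The WNT antagonists Sfrp1 (-3.68) and Sfrp2 (-3.42) fell and the BMP antagonist Grem1 (2.73) rose. With BAY-876 added, Tgfbi changed by -2.99 and Grem1 by 1.74. Pentose and hexosamine genes were higher for 6 and lower for 2 of 14 with BAY-876 (camera adjusted p = 0.245), with Pgd at 1.38 and Taldo1 at 1.05. Respiratory chain genes were higher for 16 and lower for 4 of 32 with FGF8b (camera adjusted p = 0.312), and for 9 and 5 under trimmed-mean scaling, with Cycs (cytochrome c) at 0.91 and Cox6c at -0.67. Vtn (vitronectin) had 183 reads in control and none in FGF8b plus BAY-876. With 3 reads assumed in place of none, control was 64.0-fold higher, an approximate bound without an interval.

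The fall of Ucp1 with BAY-876, by -4.67 in limma (adjusted p = 4.78e-14), was weighed against 2 explanations. Under the scaling that gave the smaller fall it was -4.6. The factors of both scalings lay between 0.945 and 1.048 over the libraries, so scaling differences of this kind are far too small to be the cause. A change in total RNA, which neither scaling measures, was not tested. For a general loss of the FGF8b response, the 777 other genes raised by FGF9 by at least 1 log2 unit were examined. The share of the response kept was the log2 change against control with BAY-876 divided by that with FGF8b alone. It is not the fraction of the RPKM level that remained. The 777 genes kept a median share of 0.97 (quartiles 0.646 and 1.305), and 134 kept a share below 0.5. Most of these genes thus stayed raised against control. Without a group of BAY-876 alone, a rise due to BAY-876 itself counts as response kept, so a general loss is not excluded. In RPKM, Ucp1 fell from 26.7 to 0.58 when BAY-876 was added to FGF8b. Its share of the log2 change moved with the treatment of low values. It was 0.13 with a pseudocount of 1 (59 of 777 genes at or below it), 0.181 with 0.5 (66) and 0.315 with 0.1 (78). With voom on recovered reads it was 0.44 (100 of 775, where the median was 0.977). A hypothesis is that the Ucp1 response to FGF8b may in part need glucose uptake through GLUT1, which FGF8b in medium with lowered glucose or in cells without Slc2a1, beside BAY-876 alone, would test.

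The fall of interferon response genes in each FGF group was weighed against heparin or handling shared by all FGF-treated libraries. The list had a median difference of -1.11 between FGF8b and FGF1. This excludes a cause equal in both as the whole cause of the fall under FGF8b and leaves open a part. For FGF1, such a cause could still be the whole of the fall. The series text gives heparin to both groups and the sample labels to neither, so the exclusion holds for heparin only if both were treated alike. Bias from GC content is excluded as well for FGF8b: the median under FGF8b was -2.61 after GC correction and -2.48 before. A share of the fall common to all FGF groups could still come from heparin, which a group with heparin alone would test.

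Within groups, the libraries deviated along a shared axis that held 31.9% of the variance within groups, with control 1, FGF9 2 and FGF8b plus BAY-876 2 at the high-GC end and control 3, FGF9 1 and FGF8b plus BAY-876 1 at the other. Across the 12594 genes with a GC value this axis correlated with GC content at 0.694, which fits a bias from library preparation or sequencing. Removing the trend with GC content left 0.829 of the variance within groups. The change from FGF8b to FGF9 correlated with GC content at 0.273, so the small differences between these ligands may partly carry this bias. Most calls outlasted the correction: of the 40 genes with a GC value that passed in limma, 38 also passed after GC correction, where 62 passed. Leaving out the 3 libraries at the high-GC end lowered the count from 41 to 15, and leaving out those at the low-GC end to 37. These cuts also leave fewer libraries, so they do not tell the bias from a loss of power.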
